A study of Silurus meridionalis with 18 samples.

How the data were processed

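The samples were 18 libraries of adult southern catfish, 1 per tissue, and the tissue was taken from each sample's label. Per the labels' protocols, total RNA was taken up in Trizol and treated with DNase I, polyadenylated RNA was selected on DynaBeads, and paired-end cDNA libraries were made with a Gnomegen kit. Per the submitters' processing notes, StringTie 1.3.4d was used. The aligner and the genome build are not given in the sources used here. The deposited table gives the authors' FPKM (fragments per kilobase of gene model and per unit of library depth), a value normalized for gene length and library depth, for 25390 genes in 18 columns, each of which named its tissue. A second deposited table gives, per gene model, its place on the assembly, its coding exons and a protein name, and served only for names, coordinates and lengths. Lengths were summed over its coding exons only, without untranslated parts. All of them are multiples of 3 (100%), with a median of 1173 bp. Whether the deposited FPKM values rest on these same lengths was not tested. Coordinates are 1-based as that table gives them, on a build not given in the sources used here.

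FPKM values are not counts, so no count model was used, and with 1 library per tissue no test was run. Depth was estimated from the low values: the smallest common step of FPKM times coding length was read as 1 fragment, which gave between 6330000 fragments in Skin and 51000000 in Gill. If the step were 1 read, these depths would be lower by a factor of 2. Only between 9.74% and 19.8% of low values lay within 0.02 steps of a whole multiple, so whole reads were not recovered and no counting interval is given. The summed FPKM ran from 457883 in Brain to 1006540 in Pancreas, so values were not scaled to a common sum. A gene listed at 0 in a library was described as such, with no ratio of its own printed, but it enters list medians of log2(FPKM + 1) and of their ratios, those of the slow-type and fast-type muscle genes included. Gene families with near-identical copies, among them the globins, keratins, trypsinogens and myosin heavy chains, can share reads, and the values of single copies are uncertain.

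All values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. The following choices were made before the data were examined. Genes were counted as detected at an FPKM of at least 1. Library similarity was the Pearson correlation of log2(FPKM + 1) over genes with an FPKM of at least 1 in any library, with average-linkage clustering on 1 minus that correlation. Tissue-enriched genes had an FPKM of at least 10 and an FPKM + 1 of at least 5 times the next-highest tissue. Group-enriched genes had every member of a fixed group at an FPKM of at least 10, and the lowest member 5 times the highest tissue outside the group. Tau was computed on log2(FPKM + 1), with 0.85 as its threshold. In each of 8 tissue pairs, genes with an FPKM of at least 5 in either library were compared, and those with a log2 ratio of FPKM + 1 of at least 2 in size were counted.

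The 43 marker lists held 747 symbols. A symbol was matched through the protein names in the deposited table, with teleost paralog suffixes allowed, and 608 symbols matched 883 gene models. The list members were fixed beforehand, but the protein names that stand for each symbol were written after the deposited tables had been opened. A list's score in a tissue was its median log2(FPKM + 1) minus the mean of the other tissues, and its percentile came from 10000 random lists of the same size drawn within 20 bins of mean expression. Genes named in the text came from a rule: the 5 named tissue-enriched genes of each tissue and the 5 of each group with the largest ratio, up to 10 named genes per direction of each pair, members of the fixed lists, and the 3 highest genes of each tissue. The lists of slow-type and fast-type muscle genes were written after the data were seen.

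Alternatives fixed beforehand were a pseudocount of 0.1, other FPKM minimums, a 10-fold or 8-fold threshold, libraries rescaled to the same sum or to the same upper quartile, related tissues averaged, Spearman correlation, list means, the highest gene model of each symbol only, and a median log2 ratio set to 0 in pairs. Leaving out the 9 mitochondrial and 18 hemoglobin gene models (with every library then rescaled to the same sum, except for library similarity), and leaving out the Testis, Skin or Muscle library, were added after seeing the data. The steps were tested on simulated data. For tissue-enriched genes, run on 25390 genes, 200 of 200 genes planted at 20-fold were recovered with 0 others called. For Ovary against Testis, run on 25390 genes, 200 of 200 genes planted at 8-fold were recovered and 15 other genes were called. The fragment step came within 1% of the simulated step in all 18 libraries. The simulated libraries held whole counts, with the same step and the same base levels in every library. They had no differences in depth or composition, so these recoveries check the code and do not measure the error in the deposited values.

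The 61 gene models of the feature table that have no FPKM value, 60 of them named odorant receptor, were not analysed here. Genes named hypothetical protein (4082) were counted but not named. The supplied reference list of gene symbols was not used here, because none of its locus tags matched the identifiers in the deposited tables. All 18 columns of the table were mapped to a sample.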

Results

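Messenger RNA was profiled in 18 tissues of the adult southern catfish, Silurus meridionalis, a bottom-living freshwater predator that lacks scales and carries long sensory barbels around the mouth. The tissues were Brain, Telecephlon (the label's spelling for the telencephalon, the front part of the brain), Olfactory_bulb, Retina, Gill, Skin, Maxillary_barbel, Mandibular_barbel, Head_kidney (the blood-forming and endocrine front part of the fish kidney), Kidney, Spleen, Heart, Muscle, Liver, Pancreas, Intestine, Ovary and Testis. Each tissue was 1 library, so no test was run, no p-value is given and no difference below has a replicate check. The values were the authors' FPKM for 25390 genes, and fold differences are given as log2 ratios of FPKM + 1, a scale that understates differences of low genes. The design names no treatment, and the comparisons are those between the tissues.

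Depth differed between libraries. The estimated number of fragments was between 48200000 and 51000000 in Brain, Gill, Head_kidney, Heart, Kidney, Liver, Ovary, Pancreas, Spleen and Testis. It was between 20200000 and 22600000 in Intestine, both barbels, Olfactory_bulb, Retina and Telecephlon, and only 9540000 in Muscle and 6330000 in Skin. Samples of like depth were numbered in sequence, and no label names a batch. Telecephlon against Brain, Retina against Brain, the barbels against Skin and Heart against Muscle cross these depth groups. There, tissue cannot be told apart from depth group. Both barbels, Olfactory_bulb with Telecephlon, and Head_kidney with Spleen lie within a group. Genes with an FPKM of at least 1 numbered 16899 in Olfactory_bulb, 16631 in Brain, 16020 in Telecephlon and 15855 in Kidney, against 6682 in Ovary, 6297 in Muscle and 5740 in Pancreas. In Pancreas the 10 highest genes held 64.7% of the summed FPKM, led by the digestive proenzymes trypsinogen (C0J45_20044, FPKM 130196; C0J45_04204, 79770) and by syncollin-like (C0J45_13912, 76172), a zymogen granule protein. In Testis the 10 highest genes held 63.5%, and mitochondrially encoded transcripts alone held 62.9% of the summed FPKM, led by cytochrome c oxidase subunit I (C0J45_25303, 122692). The mitochondrial share was 11.7% in Heart, 6.60% in Brain, 0.375% in Skin and 0.0710% in Muscle. Hemoglobin genes held 37.0% of the summed FPKM in Head_kidney, 24.1% in Spleen and 23.6% in Kidney. Ribosomal protein genes held 55.6% in Skin and 39.1% in Ovary, against 5.91% in Pancreas.

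**Figure D1:**
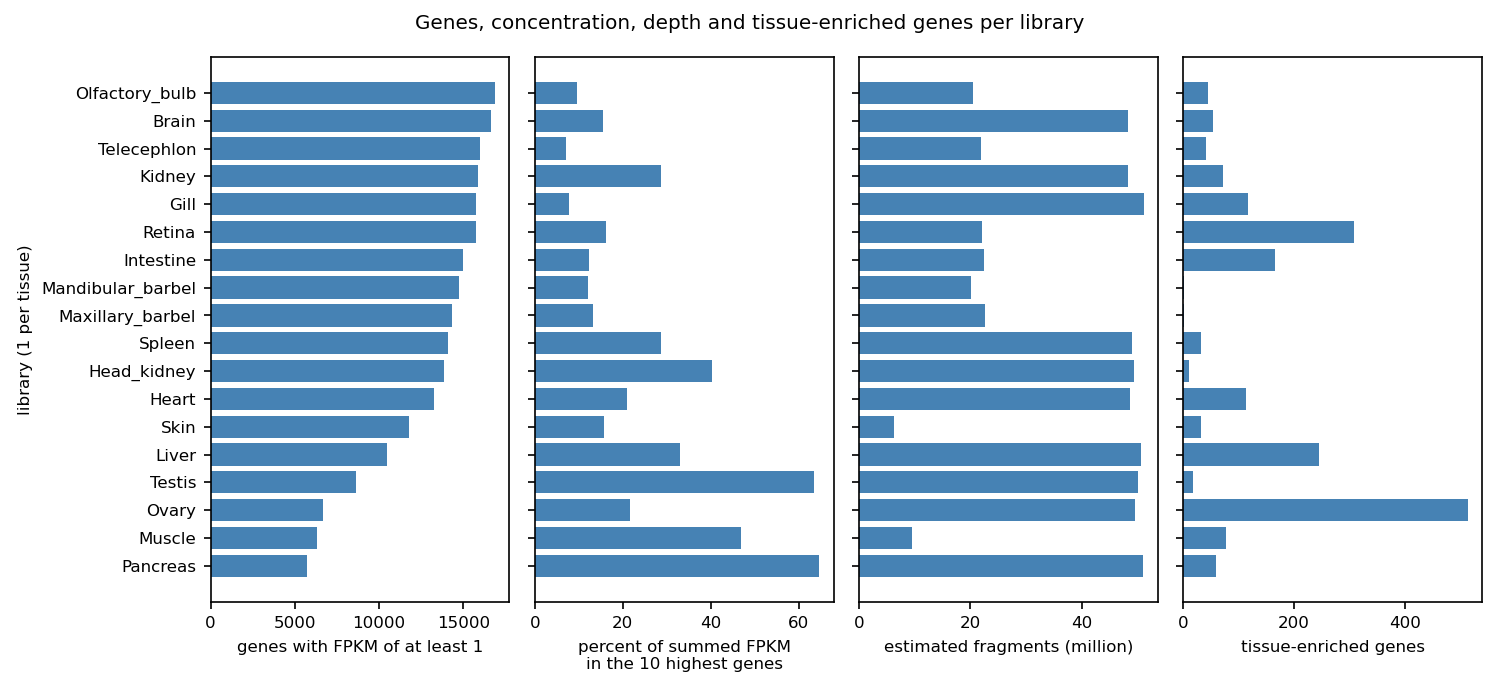
Bars give, for each of the 18 libraries, the genes with an FPKM of at least 1, the percent of the summed FPKM in the 10 highest genes, the estimated number of fragments and the number of tissue-enriched genes. Pancreas had the fewest detected genes (5740) and Ovary the most tissue-enriched genes (513).

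Both barbels with Gill, the brain parts, and the kidneys with Spleen were the closest libraries, while Heart, Testis and Intestine lay nearest to libraries of unlike organs. Across genes, the Pearson correlation of log2(FPKM + 1) was 0.984 between the Maxillary_barbel and Mandibular_barbel libraries, the yardstick for like tissues here, and genes are not independent replicates. Olfactory_bulb and Telecephlon correlated at 0.925, Head_kidney and Spleen at 0.913, and Brain and Telecephlon at 0.905. Kidney lay closest to Head_kidney (0.881), Gill to Mandibular_barbel (0.874), Retina to Brain (0.785), Intestine to Kidney (0.787), Heart to Spleen (0.789), and Liver and Pancreas to each other (0.703). Skin lay about equally close to Muscle (0.7674) and to Maxillary_barbel (0.7670), and their order turned once mitochondrial and hemoglobin genes were left out, a choice made after seeing the data. Testis lay closest to Spleen (0.740), and Ovary, whose nearest library was Testis at 0.576, joined the tree last. With only the 2598 genes that had an FPKM of at least 1 in every library, the nearest library was the same for 11 of the 18, and Ovary lay closest to Skin and Testis to Intestine.

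**Figure D2:**
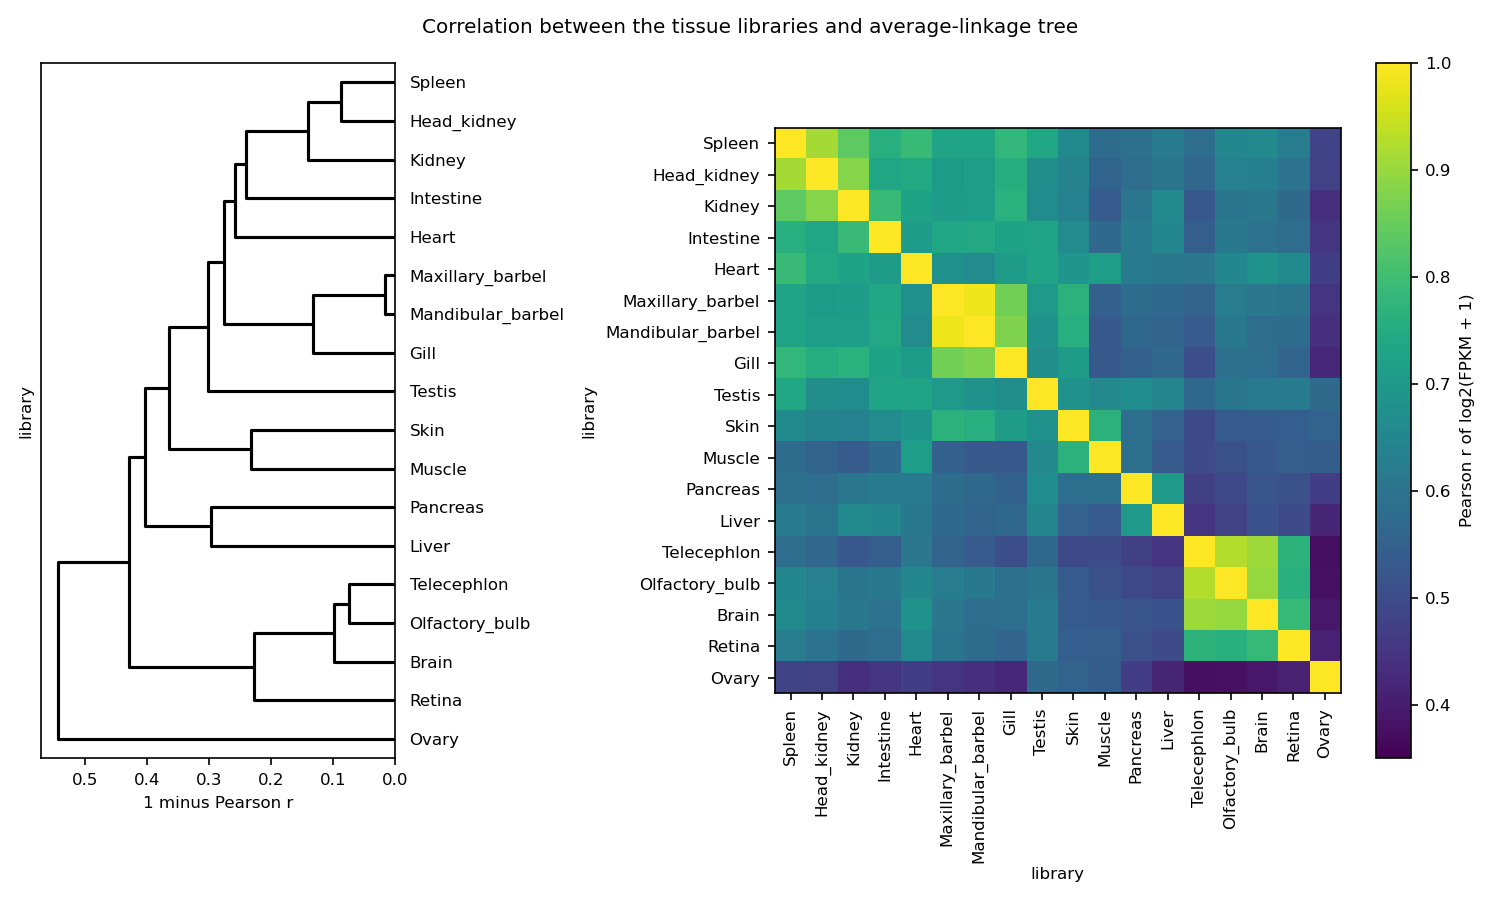
The average-linkage tree on 1 minus the Pearson correlation of log2(FPKM + 1) stands beside the correlations of all library pairs. Both barbels (0.984), the brain parts with Retina, and Head_kidney with Spleen (0.913) form blocks, and Ovary joins last.

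A gene was called tissue-enriched when its FPKM was at least 10 and its FPKM + 1 was at least 5 times that of the next-highest tissue. Of 1907 such genes, Ovary held 513, Retina 308, Liver 245, Intestine 165, Gill 117, Heart 114, Muscle 77, Kidney 71, Pancreas 60, Brain 53, Olfactory_bulb 45, Telecephlon 42, Skin 33, Spleen 32, Testis 17, Head_kidney 11 and each barbel 2. With related tissues averaged, the brain parts held 357 and the barbels 83, far above their separate counts, while Kidney and Head_kidney together held 83, close to theirs. Tau, an index from 0 for even expression to 1 for expression in a single tissue, had a median of 0.613 over 22197 genes, and 4641 genes (20.9%) reached 0.85. The count for Ovary was 264 and that for Testis 39 when libraries were scaled to the same upper quartile, and Skin held 59 without the Muscle library.

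Among the neural tissues, myelin genes were among the leading genes of Brain and phototransduction genes led Retina. Myelin basic protein (C0J45_18875, chromosome 22 from 6223392 to 6257012, 6 coding exons), a structural protein of the myelin sheath, had an FPKM of 7447 in Brain against 455 in Telecephlon. Myelin protein P0 (C0J45_17751) stood at 4768 in Brain and 324 in the next tissue, and apolipoprotein D (C0J45_18095), a lipid carrier, at 296 in Brain and 17.4 in Retina. Ependymin (C0J45_21567), a secreted glycoprotein of the fish brain fluid, was the highest gene in Brain at 21925 and stood at 11907 in Olfactory_bulb and 4468 in Telecephlon. Olfactory_bulb was led by secretagogin (C0J45_10141, chromosome 10 from 20570024 to 20576378), a calcium-binding protein, at 378 against 1.55, and by matrilin-3 (C0J45_01898) at 191 against 0.613. Telecephlon was led by complement C1q-like protein 3 (C0J45_17530), a secreted synaptic protein, at 166 against 1.61 and by reticulon-4 receptor-like 2 (C0J45_01304) at 256 against 9.17. Rhodopsin (C0J45_09052, chromosome 9 from 18458474 to 18459538, 1 coding exon), the rod visual pigment, was the highest gene of Retina at 34592, against 0.661 in the next tissue. Red-sensitive opsin-1 (C0J45_17147), a cone pigment, stood at 2894 in Retina.

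In the blood-forming, filtering and secretory organs, Head_kidney genes were led by enzymes of steroid and catecholamine synthesis. Steroid 21-hydroxylase-like (C0J45_03997, chromosome 4 from 10597551 to 10601448, 11 coding exons), which acts in cortisol synthesis, stood at 865 in Head_kidney against 1.11 in the next tissue, and phenylethanolamine N-methyltransferase (C0J45_06667), which makes adrenaline, at 59.6 against 1.75. Kidney was led by sulfotransferase 1C1 (C0J45_06763) at 234 and held solute carrier family 22 member 6 (C0J45_14019), an organic anion transporter of the renal tubule, at 341 against 1.31. Spleen was led by T-cell leukemia homeobox protein 1 (C0J45_01499), a transcription factor needed for spleen formation, at 95.9 against 0.257, followed by T-box 2a (C0J45_19045) at 68.8. Liver was led by hemopexin (C0J45_02696, chromosome 3 from 9501300 to 9503936, 9 coding exons), a plasma heme carrier, at 65773 against 34.9 in Pancreas, and held apolipoprotein A-I (C0J45_17850) at 37922. Pancreas was led by chymotrypsin B1 (C0J45_09708) at 58240 against 22.1 in Liver and elastase 3 like (C0J45_19051) at 43176. Intestine was led by cathepsin L.1 (C0J45_08386), a cysteine protease, at 1088 against 0.188 and guanylate cyclase activator 2B (uroguanylin) (C0J45_17093), a gut peptide that acts on salt secretion, at 570. Gill was led by collagen alpha-1(X) chain (C0J45_16658), a cartilage and bone collagen, at 710 against 1.54, and held the transcription factor paired box protein Pax-1 (C0J45_20165), known from pharyngeal arches, at 71.0 while every other tissue was listed at 0.

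Heart and Muscle were each led by their own forms of the contractile proteins. Myosin regulatory light chain 2, atrial isoform (C0J45_15206, chromosome 17 from 2734551 to 2737092) had an FPKM of 17334 in Heart against 5.15 in the next tissue, and natriuretic peptides A (C0J45_15329), a hormone precursor released by the atrium, stood at 8747. Tropomyosin alpha-1 chain (C0J45_08975) stood at 17803 in Muscle against 103 in Skin, and myosin regulatory light chain 2, skeletal muscle isoform (C0J45_12784) at 52192 against 344 in Skin. Skin itself was led by muscle genes: sarcoplasmic/endoplasmic reticulum calcium ATPase 1 (C0J45_12881) stood at 287 against 2.58 in Muscle, slow myosin heavy chain 3 (C0J45_04426) at 773 against 12.1 in Gill, and troponin C type 1b (slow) (C0J45_14596) at 1503 against 34.7 in Muscle. Keratin 4 (C0J45_14629) was the only epidermal gene among the 5 leading genes of Skin, at 359 against 6.74.

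In the gonads, Ovary was led by H2A histone family member 1a like (C0J45_20837, chromosome 24 from 13317880 to 13318302, 1 coding exon), at 31302 against 3.17, by linker histone H1M (C0J45_21020), an egg-type linker histone, at 12465 and by the egg coat gene zona pellucida glycoprotein 2, like 1 (C0J45_11814) at 9573. Testis was led by CD59 glycoprotein-like (C0J45_17643) at 371 and transcription factor 23 (C0J45_00132) at 140. Gonadal somatic cell derived factor (C0J45_19250), a signal of fish gonadal support cells, stood at 172 against 9.86. No leading Testis gene was a sperm structural gene, and mitochondrial transcripts took 62.9% of this library.

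Genes shared by related tissues were counted where the lowest member of a fixed group was at least 5 times the highest tissue outside it. Summed over the groups there were 338: 171 were neural (the brain parts and Retina), 61 were of the barbels, 36 of the brain parts, 34 of Head_kidney, Kidney and Spleen, 21 of Heart and Muscle, 14 of the body surface and 1 of the gonads. The brain parts lie within the neural group and the barbels within the body surface, so a gene can count more than once. Total counts of group-enriched genes below are such sums too. The neural group was led by synaptophysin b (C0J45_15291), a synaptic vesicle protein, at 443 in Telecephlon, 330 in Retina, 240 in Olfactory_bulb and 143 in Brain, and held synaptosomal-associated protein 25-A (C0J45_19735), which drives vesicle fusion, at 1302 in Telecephlon. The barbels shared peptidase inhibitor 16-like (C0J45_14978) at 365 in Mandibular_barbel and 338 in Maxillary_barbel, and angiopoietin-related protein 7 (C0J45_09013) at 211 and 430. The body surface shared keratin 92 (C0J45_18677) at 5385, 6992 and 3039 in Mandibular_barbel, Maxillary_barbel and Skin, and the gel-forming mucin-5B (C0J45_09447) at 30.2, 31.1 and 24.7. Heart and Muscle shared LIM domain-binding protein 3 (C0J45_01349), a Z-disc protein, at 90.4 and 67.8. The gonads shared only enkurin (C0J45_24439), a protein of sperm and motile cilia, at 85.1 in Ovary and 16.8 in Testis. Leaving out the Skin library, a choice made after seeing the data, gave 63 genes for Heart and Muscle, and rescaling each library to the same sum gave 109 for the brain parts and 362 for the neural group.

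Of 43 marker gene lists fixed before the data were examined, 40 named a tissue, and 29 of these had their highest median in a named tissue. The list medians of log2(FPKM + 1) were 12.82 for exocrine pancreas in Pancreas, 10.24 for liver secreted and metabolic genes in Liver, 8.78 for rod and 7.19 for cone phototransduction in Retina, 7.76 for the erythroid list and 7.55 for interrenal steroidogenesis in Head_kidney, and 7.21 for the oocyte list in Ovary. They were 6.50 for keratinocytes in Maxillary_barbel, 6.06 for cardiac muscle in Heart, 5.91 for neurons in Telecephlon, 5.91 for intestinal epithelium in Intestine, 5.80 for skeletal muscle in Muscle, 5.74 for central glia and myelin in Brain, 4.99 for gill ionocytes in Gill and 4.96 for kidney tubule and glomerulus in Kidney. Each of these lists lay at the percentile of 100 among 10000 random lists of the same size matched on mean expression, as a description of these libraries. The telencephalic regulators (2.94) were highest in Olfactory_bulb, the mid- and hindbrain regulators (1.77) and the hypothalamus and pituitary hormones (0.15, percentile 93.9) in Brain, and inner retina (4.77), retinal pigment epithelium (3.30) and non-visual opsins (2.04) in Retina. Granulocyte (2.94) and B cell (2.52) lists were highest in Head_kidney, T cell (4.32) and macrophage (4.34) lists in Spleen, taste cells (1.32) in Mandibular_barbel, and peripheral nerve and Schwann cells (2.53, percentile 98.1) in Maxillary_barbel. The peripheral nerve list was instead highest in Brain with list means, with equal upper quartiles and with the highest gene model of each symbol. The telencephalic regulators were highest in Telecephlon with list means and with the highest gene model of each symbol, the hormones in Retina with list means, and the macrophage list in Kidney with equal upper quartiles. The germline list was highest in Ovary (1.55) and stood at 0.60 in Testis, while testicular somatic cells stood at 3.33 in Testis.

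The other 11 lists were highest elsewhere. No library was labelled lens or olfactory epithelium, so lens was looked for in Retina and olfactory sensory neurons in Olfactory_bulb. The sperm and spermatid list, looked for in Testis, had its highest median in Kidney (2.46), where its member radial spoke head 1 homolog (C0J45_02901), a part of motile cilia, stood at 16.2. Cartilage was highest in Gill (3.32), mucus cells in Maxillary_barbel (3.50), and pigment cells (2.17), olfactory sensory neurons (2.37), chromaffin cells (2.02), endocrine pancreas (1.07) and hair cells (0.36) in Retina. Ovarian somatic cells (0.35, in Testis), lens (0.09, in Telecephlon) and vitellogenins (0.07, in Gill) were low in every library. With equal upper quartiles, endocrine pancreas was highest in Pancreas and vitellogenins in Liver, their own tissues. Of the lists tied to no tissue, cell proliferation was highest in Ovary (4.86), the circadian clock in Telecephlon (3.51) and broadly expressed reference genes in Intestine (9.18).

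**Figure D3:**
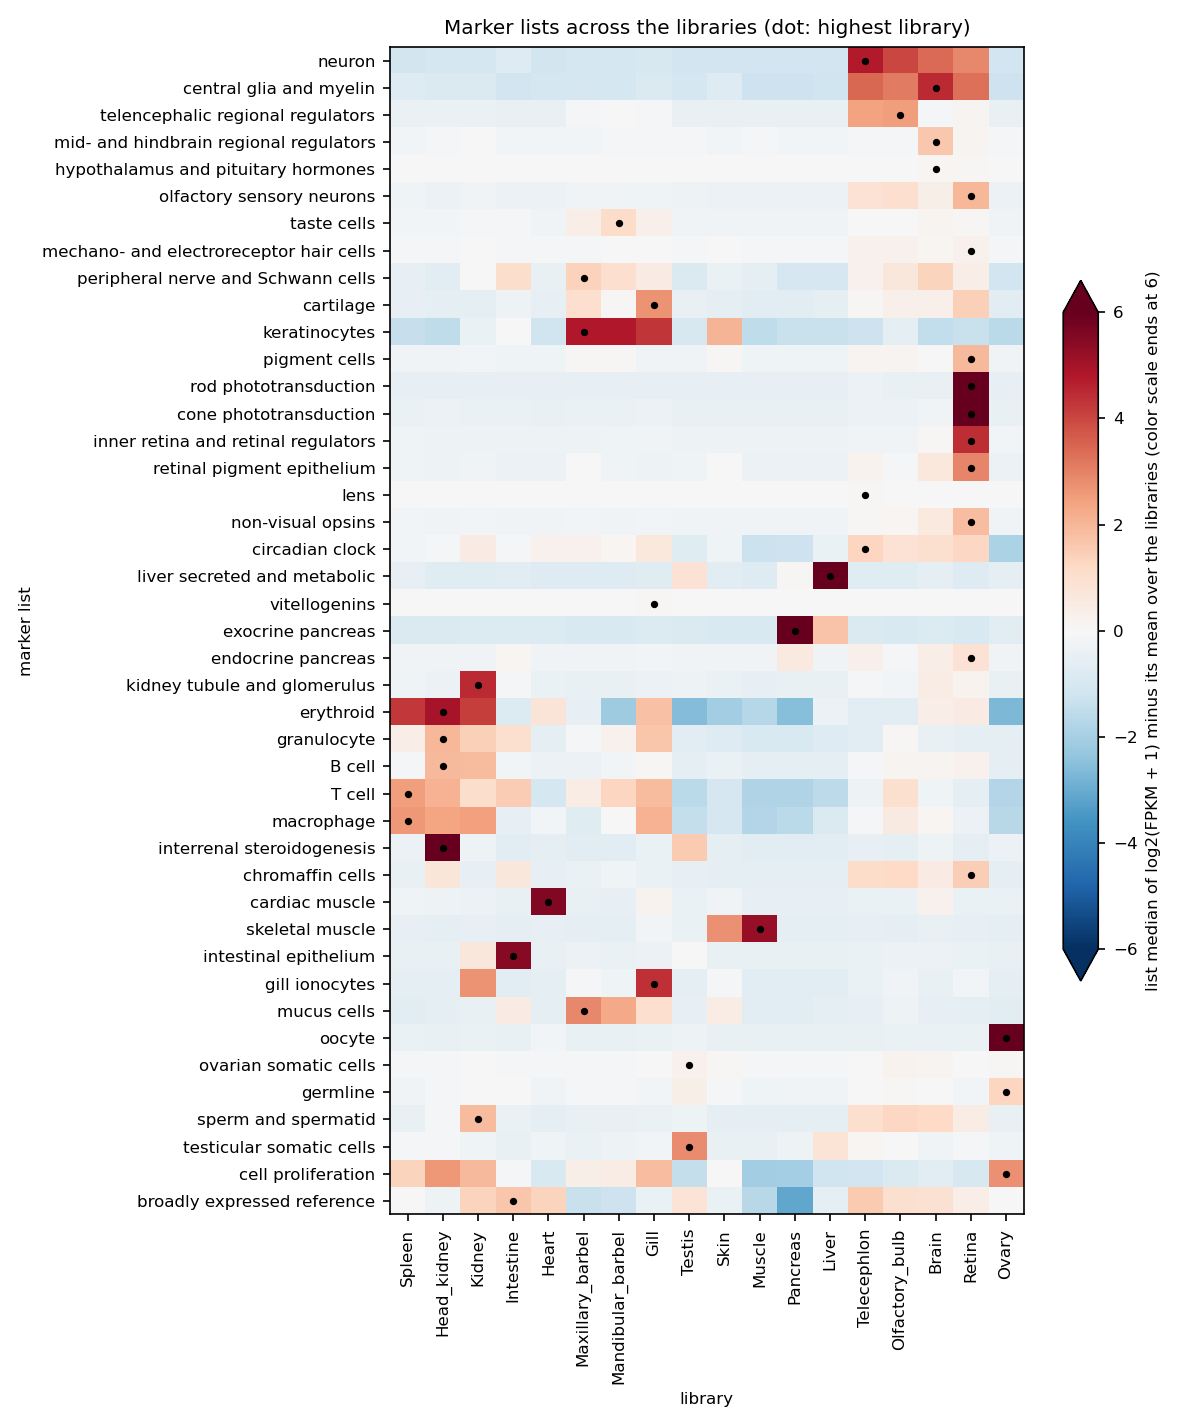
Colors give each marker list's median log2(FPKM + 1) in a library minus its mean over the 18 libraries, and the dot marks the library with the highest median. For 29 of the 40 lists with a named tissue the dot falls in that tissue, and the sperm and spermatid dot falls in Kidney (2.46).

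Ovary against Testis asks how the gonads of the sexes differ. Oocyte and cell proliferation genes were higher in Ovary, and testicular somatic genes, like those of many unrelated lists, were higher in Testis. H2A histone family member 1a like (C0J45_20837) had a log2 ratio of 13.93, zona pellucida glycoprotein 2, like 1 (C0J45_11814) of 13.12 and linker histone H1M (C0J45_21020) of 12.35. Of 18 oocyte list members with an FPKM of at least 5 in either library, 17 were at least 4-fold higher in Ovary and 1 in Testis (list median 6.67), and all 14 cell proliferation members were higher in Ovary (4.22). Of 7 germline members, 6 were higher in Ovary and none in Testis (median 0.68). Of 8 testicular somatic members, 7 were higher in Testis (median -2.18), and of 7 interrenal steroidogenesis members 5 were higher in Testis and 1 in Ovary (-1.71). The testicular somatic and interrenal lists share members, star among them, and are not independent. Lists of other tissues went the same way, with 6 of 6 macrophage, 6 of 7 granulocyte, 7 of 8 cardiac muscle, 6 of 7 skeletal muscle, 7 of 9 keratinocyte, 6 of 7 intestinal epithelium and 9 of 13 liver members higher in Testis. On the Testis side, alcohol dehydrogenase 8a (C0J45_01705) stood at 605 against 3.72, CCAAT/enhancer-binding protein beta (C0J45_15653), a transcription factor, had a log2 ratio of -6.72, and transgelin (C0J45_17954), an actin-binding protein of smooth muscle, of -6.27 with an FPKM of 4600 in Testis. Among 5242 genes compared, 2195 were at least 4-fold higher in Ovary and 1274 in Testis, so that 63.3% of the differing genes were higher in Ovary. The median log2 ratio of genes with an FPKM of at least 5 in both was 1.12; with that median set to 0 the share higher in Ovary was 42.9%, and with mitochondrial and hemoglobin genes left out and both libraries rescaled to the same sum, chosen after seeing the data, it was 29.6%. With equal upper quartiles the germline list had its highest median in Testis.

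Maxillary_barbel against Mandibular_barbel compares the long upper with the shorter lower barbels. Both libraries were led by keratin 4 (C0J45_00982, FPKM 26435 and 21978) and ictacalcin (C0J45_03742, 9741 and 8729), a calcium-binding protein of fish epithelia. Both correlated more with Gill (0.862 and 0.874) than with Skin (0.767 and 0.757). The Skin library had the lowest depth, a ribosomal protein share of 55.6% and muscle genes. Whether the order of Gill and Skin lies in the tissue or in that library was not tested. Among the genes higher in Maxillary_barbel, collagen alpha-2(VIII) chain (C0J45_02664) had a log2 ratio of 3.78, aggrecan core protein (C0J45_05257), the main cartilage proteoglycan, of 3.44 (228 against 20.1), and elastin a (C0J45_17854) of 2.99. Hemoglobin subunit beta-1 (C0J45_19307) was also higher there, at 890 against 107. In Mandibular_barbel, a pair of ladderlectin-like lectin genes (C0J45_06619, 317; C0J45_06617, 58.8) were listed at 0 in Maxillary_barbel, and growth/differentiation factor 8 (C0J45_18909), the muscle growth inhibitor myostatin, stood at 73.5 against 9.18 (log2 ratio -2.87). Of 9962 genes compared, only 34 were at least 4-fold higher in Maxillary_barbel and 28 in Mandibular_barbel, and the median shift was -0.07. Of 9 cartilage members, 3 were higher in Maxillary_barbel, as were 3 of 4 erythroid members, whose list median was 1.39, and 2 of 7 peripheral nerve members (0.44). The T cell (-0.86), macrophage (-0.47) and taste cell (-0.47) medians went the other way, with no compared member 4-fold apart.

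The mean of both barbels against Skin compares the sensory appendages with the general body surface. Most keratinocyte, Schwann cell and cartilage genes, like part of the genes of other lists, were higher in the barbels, and muscle genes were higher in Skin. In the Skin library the mitochondrial share was 0.375%, the ribosomal protein share was 55.6% and the depth the lowest of all libraries. An ictacalcin gene (C0J45_03739) stood at 3958 in the barbels against 12.9 in Skin (log2 ratio 8.15), annexin A5 (C0J45_03456) at 423 against 2.13, and myelin protein P0 (C0J45_17751), the main protein of peripheral myelin, at 174 against 0.35. Of 23 keratinocyte members with an FPKM of at least 5, 17 were higher in the barbels and 3 in Skin (list median 2.14), and of 9 peripheral nerve members 6 were higher in the barbels and 1 in Skin (1.36). Of 8 cartilage members 6 were higher in the barbels and 1 in Skin (0.69). Of immune lists, 5 of 10 macrophage (0.71) and 4 of 5 granulocyte members (0.66) were higher in the barbels and none in Skin, against 1 of 6 T cell members, and no B cell member reached an FPKM of 5. Mitochondrially encoded NADH dehydrogenase subunit 4 (C0J45_25298, 507 against 0.971) and subunit 3 (C0J45_25300, 2674 against 15.2) were also among the leading genes of the barbels. Other lists went the same way, with 9 of 10 central glia and myelin members and 7 of 14 circadian clock members higher in the barbels. In Skin, 1 glia and no clock member was higher. The broadly expressed reference median was 0.82 at percentile 50.3, above the cartilage, macrophage and granulocyte medians. Among matched random lists, keratinocytes lay at percentile 100, cartilage at 99.2, peripheral nerve at 98.5, macrophages at 97.2 and granulocytes at 93.0. Of 26 skeletal muscle members, 25 were higher in Skin and 1 in the barbels (median -3.25). In Skin, creatine kinase of muscle type (C0J45_21610) stood at 1696 against 0.09, troponin C type 1b (slow) (C0J45_14596) had a log2 ratio of -10.50, slow myosin heavy chain 3 (C0J45_04426) of -9.58, and myoglobin (C0J45_20474) stood at 574 against 0.12. Among 10215 genes, 2815 were at least 4-fold higher in the barbels and 372 in Skin, a share of 88.3% higher in the barbels. The median shift was 0.53, and with it set to 0 that share was 76.6%. Over lists of muscle genes written after the data were seen, the median log2 ratio of Skin to Muscle was 4.78 for 12 slow-type gene models and -4.56 for 18 fast-type ones.

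**Figure D4:**
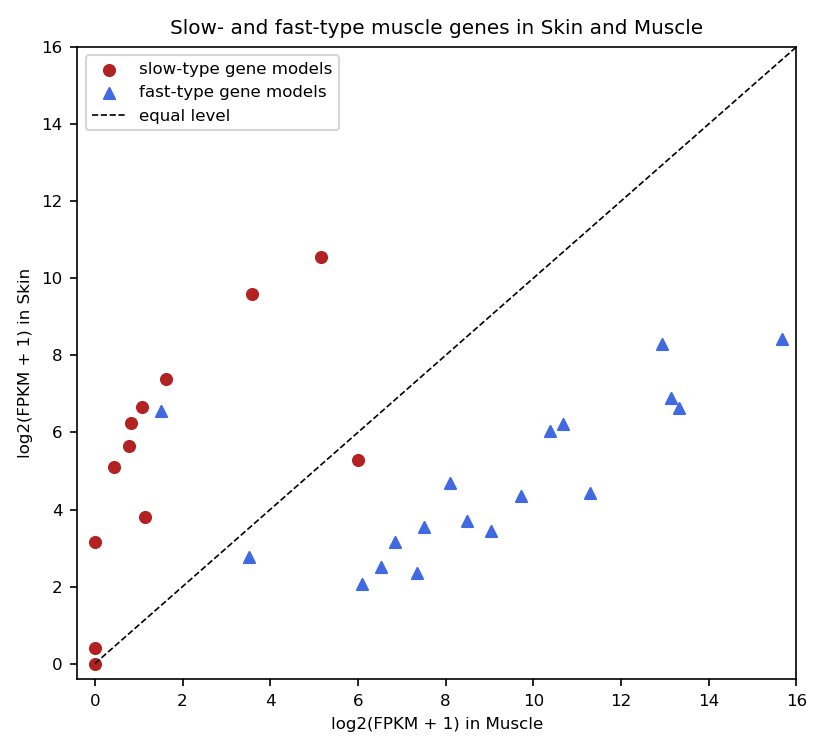
Each point is a gene model of a slow-type (circles) or fast-type (triangles) muscle protein, at its log2(FPKM + 1) in Muscle and in Skin, with a dashed line at equal level. Slow-type genes lie mostly above the line (median log2 ratio of Skin to Muscle 4.78) and fast-type genes mostly below it (-4.56).

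Kidney against Head_kidney sets the filtering kidney beside the blood-forming and endocrine kidney. Transport genes of the tubule were higher in Kidney, and the steroid synthesis pathway was higher in Head_kidney. Solute carrier family 22 member 6 (C0J45_14019) had a log2 ratio of 8.40, cadherin-17 (C0J45_18395) of 8.47 and protein S100-A11 (C0J45_23274) of 9.09, while collectrin (C0J45_15065), a partner of amino acid transporters, stood at 255 in Kidney and was listed at 0 in Head_kidney. Of 20 kidney tubule and glomerulus members, 17 were at least 4-fold higher in Kidney (list median 4.72), as were 10 of 12 sperm and spermatid members (1.80), which code largely for parts of motile cilia. Steroidogenic acute regulatory protein (C0J45_15133), which carries cholesterol into mitochondria, had a log2 ratio of -9.30, steroid 21-hydroxylase-like (C0J45_03997) of -9.54 and ferredoxin 1b (C0J45_21676), an electron carrier to steroid-forming enzymes, of -6.77. Of 10 interrenal members, 9 were higher in Head_kidney (median -6.66), and all 4 chromaffin members were higher there too (-0.98). Blood cell genes differed less: none of 10 erythroid (median -0.89), 12 granulocyte (-0.43) or 8 B cell members (-0.18) was 4-fold higher in Head_kidney, and 1 granulocyte and 1 B cell member were higher in Kidney. Lists of other epithelia went with Kidney, with 12 of 15 intestinal and 7 of 9 gill ionocyte members higher there. Of 10900 genes compared, 967 were higher in Kidney and only 48 in Head_kidney, with a median shift of -0.04. In all 1015 genes differed, against 1569 with mitochondrial and hemoglobin genes left out and the libraries rescaled to the same sum, chosen after seeing the data.

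Telecephlon against Brain compares a part of the forebrain with the brain library. Regional transcription factors of the telencephalon and part of the neuron genes were higher in Telecephlon, and part of the glial genes and most mid- and hindbrain regulators were higher in Brain. Class E basic helix-loop-helix protein 23 (C0J45_14701), a neural transcription factor, had a log2 ratio of 7.15 (FPKM 330 against 1.33), somatostatin (C0J45_11186), a neuropeptide, of 6.94 and forkhead box G1 (C0J45_07830), a regulator of telencephalon formation, of 5.18. All 15 telencephalic regulators with an FPKM of at least 5 were higher in Telecephlon (list median 2.64), and of 32 neuron members 10 were higher in Telecephlon and 2 in Brain (1.26). Natriuretic peptide C (C0J45_08705) had a log2 ratio of -6.45, apolipoprotein D (C0J45_18095) of -5.82 and peripheral myelin protein 22 (C0J45_07395) of -5.68. Of 14 central glia and myelin members, 7 were higher in Brain and none in Telecephlon (median -0.31), and of 10 mid- and hindbrain regulators 8 were higher in Brain (-1.48). Of 12032 genes, 441 were higher in Telecephlon and 359 in Brain, with a median shift of 0.16.

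Olfactory_bulb against Telecephlon compares the first relay of smell with the telencephalon. The libraries correlated at 0.925. Secretagogin (C0J45_10141) had a log2 ratio of 7.22, matrilin-3 (C0J45_01898) of 6.89, anosmin 1b (C0J45_09220), an extracellular protein of the olfactory system, of 6.05, cortistatin (C0J45_14423) of 5.88 and the homeobox gene Dlx2b (C0J45_20645) of 5.28. In Telecephlon, the bHLH regulators neurogenic differentiation factor 6-A (C0J45_04201) and neurogenic differentiation factor 2 (C0J45_06783) had log2 ratios of -6.77 and -6.58, and somatostatin (C0J45_11186) stood at 1037 in Telecephlon while it was listed at 0 in Olfactory_bulb. The 20 telencephalic regulators split evenly, with 7 higher in each library. Of 30 neuron members, 4 were higher in Telecephlon and 1 in Olfactory_bulb (list median -0.75), and none of 13 macrophage members was 4-fold apart although their median was 0.82. Of 12207 genes, 252 were higher in Olfactory_bulb and 287 in Telecephlon.

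Heart against Muscle compares cardiac with skeletal muscle. Cardiac contractile genes were higher in Heart and skeletal contractile genes in Muscle, the leading ones with levels at or near 0 in the other library. The atrial myosin regulatory light chain (C0J45_15206), cardiac myosin light chain-1 (C0J45_22362, FPKM 14604 in Heart) and natriuretic peptides A (C0J45_15329) were listed at 0 in Muscle. The mitochondrially encoded cytochrome c oxidase subunit II (C0J45_25302) stood at 19271 against 4.85, a log2 ratio of 11.69. Mitochondrial transcripts held only 0.0710% of the summed FPKM in Muscle against 11.7% in Heart, and were also low in Skin (0.375%) and Pancreas (0.264%). Whether this difference lies in the tissue or in the library was not tested. In Muscle, the skeletal myosin regulatory light chain (C0J45_12784) had a log2 ratio of -15.44, myosin, light polypeptide 3 (C0J45_20952) of -14.57, parvalbumin-7 (C0J45_22132), a calcium buffer of fast fibres, of -13.78, and troponin T of fast skeletal muscle (C0J45_09932) of -12.94. Of 28 cardiac muscle members, 23 were higher in Heart and 3 in Muscle (list median 5.34); of 29 skeletal muscle members, 28 were higher in Muscle and none in Heart (-4.42). Of 7797 genes, 4065 were higher in Heart and 224 in Muscle, and lists of other cell types went with most genes: all 7 erythroid members (2.86), all 9 macrophage members (percentile 91.4) and all 5 B cell members (0.24) were higher in Heart. The median shift was 0.85, and 2261 genes differed 4-fold in either direction with that median set to 0, against 4289 without and 7080 with mitochondrial and hemoglobin genes left out and the libraries rescaled to the same sum.

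Retina against Brain compares a sensory neural tissue with the brain. Rod and cone genes were higher in Retina, and most central glia and myelin genes were higher in Brain. Rhodopsin (C0J45_09052) had a log2 ratio of 15.05, the rod phosphodiesterase gamma subunit (C0J45_07326), which restrains the visual cascade, of 12.38 and arrestin-C (C0J45_11063), a cone arrestin, of 10.61. Transducin alpha-1 (C0J45_00408, FPKM 3101), red-sensitive opsin-1 (C0J45_17147, 2894) and phosducin (C0J45_11672, 2460) were listed at 0 in Brain. All 25 rod members (list median 8.68), 10 of 11 cone members (7.11), 13 of 16 inner retina members (4.27), 9 of 14 pigment epithelium members (1.75) and 7 of 8 pigment cell members (1.76) were higher in Retina. The pigment epithelium and pigment cell lists share members, tyr, dct, pmel and mitf among them, and are not independent. Ependymin (C0J45_21567) had a log2 ratio of -14.28, myelin basic protein (C0J45_18875) of -8.29, and sodium- and chloride-dependent GABA transporter 3 (C0J45_17069) of -7.33. Of 16 central glia and myelin members, 11 were higher in Brain and 2 in Retina (median -2.15), and of 31 neuron members 11 were higher in Brain and 3 in Retina (-1.36). Of 12068 genes, 811 were higher in Retina and 793 in Brain, a share of 50.6% higher in Retina that was 39.3% with mitochondrial and hemoglobin genes left out and both libraries rescaled to the same sum, chosen after seeing the data.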

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

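The values without mitochondrial and hemoglobin genes and those without a library were chosen after seeing the data. No paired analysis was possible because each tissue is 1 library without replicate numbers. Of 80 alternative values of the main counts, 56 stayed within 1.5 times the count first given (within its 95% binomial interval for the share of tissue-specific genes) and 24 did not; of the gene counts per tissue, group or direction of a pair, 302 stayed within 1.5 times and 80 did not. Of the shares higher in the first library of a pair, 34 stayed within 10 percentage points and 6 did not. No bound was set for the 26 alternative values of 5 library correlations and of the median tau; the correlation of Ovary and Testis ran from 0.523 to 0.626. Stricter thresholds lower counts by construction: an FPKM of at least 5 gave a median of 9079 detected genes per tissue against 14226, a 10-fold threshold gave 1144 tissue-enriched and 135 group-enriched genes against 1907 and 338, and an 8-fold threshold in the pairs gave 1973 genes for Ovary and Testis, 10 for the barbels, 1182 for barbels and Skin, 579 for Kidney and Head_kidney, 247 for Telecephlon and Brain, 183 for Olfactory_bulb and Telecephlon, 1779 for Heart and Muscle and 724 for Retina and Brain. Rescaling every library to the same sum gave 598 group-enriched genes, and the same rescaling after leaving out mitochondrial and hemoglobin genes also gave 598. That omission with its rescaling gave 5391 differing genes for Ovary and Testis against 3469, 1569 for Kidney and Head_kidney against 1015 and 7080 for Heart and Muscle against 4289, while setting the median ratio to 0 gave 2261 for Heart and Muscle. Rescaling multiplies each library by its own factor, which shifts every ratio of a pair and changes which genes pass the fixed FPKM minimum. For the pairs, rescaling without the omission was not run. The share of genes with tau of at least 0.85 was 10.1% with a pseudocount of 0.1 and 16.8% over genes reaching an FPKM of 10. It was 24.9% with related tissues averaged, and 19.8%, 20.1% and 19.4% without Testis, Skin and Muscle, against 20.9%. The smaller pseudocount gives low values above 0 more weight, so by construction tau falls or stays the same. The other settings change the genes or the tissues counted, and what moved their shares was not tested. With genes at an FPKM of at least 1 in all libraries, 11 libraries kept their nearest library. The number of lists highest in a named tissue was 27 with list means, 28 with the highest gene model of each symbol, 28 without Testis or without Muscle, and 29 in the other settings run. With a library left out, lists naming only that tissue were not counted. The lower number without Testis or Muscle comes from this, and no counted list lost its named tissue there. Of the tissue-enriched genes, 1756 were shared with the rescaling to the same sum and 1549 with equal upper quartiles. Depth limits Skin and Muscle most, with 6330000 and 9540000 fragments.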

Other observations

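The tests of explanations in this part were all chosen after the results they bear on had been seen, as were the lists of slow-type and fast-type muscle genes and the genes singled out here. Single genes of several cell types add detail to the lists above. Gill held the ammonia transporter Rhbg (C0J45_04094) at an FPKM of 1086, Rhcg (C0J45_09915) at 232 and the transcription factor gcm2 (C0J45_18363) at 88.1. Pancreas held islet hormones beside its digestive enzymes, with insulin (C0J45_21548) at 534 and glucagon (C0J45_22159) at 229. Head_kidney led in nephrosin (C0J45_21771, 4545), a granulocyte protease, and in cd79b (C0J45_06839, 162), a part of the B cell receptor, while Spleen led in cd74 (C0J45_10016, 6664), which escorts class II antigen-presenting molecules, and in hmox1 (C0J45_13082, 271), which breaks down heme. The taste receptor gene tas1r3 (C0J45_16866) stood at 3.20 in Mandibular_barbel and 1.52 in Maxillary_barbel, and the taste channel trpm5 (C0J45_21838) at 4.26 and 1.86.

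Among single genes of the clock and opsin lists, period 3 (C0J45_16883) stood at 159 in Mandibular_barbel and 132 in Maxillary_barbel, aanat (C0J45_00240), an enzyme of melatonin synthesis, stood at 446 in Retina, and peropsin (C0J45_01708), an opsin of the retinal pigment epithelium, stood at 343 in Intestine. A second rhodopsin gene (C0J45_17276) reached 438 in Retina. In Olfactory_bulb, gad1 (C0J45_00895), which makes GABA, stood at 192 and tyrosine hydroxylase (C0J45_09951), of dopamine synthesis, at 87.9, against 21.8 for the latter in Head_kidney.

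Genes of sperm and germ cells were low in the Testis library, in which mitochondrial transcripts held 62.9% of the summed FPKM. Dilution by mitochondrial transcripts might lower them. With the mitochondrial genes left out and every library rescaled to the same sum, the sperm and spermatid median in Testis still lay -2.27 (log2) from the highest other library (0.77 against 3.04 in Kidney), which argues against dilution of the sperm genes as the whole account, while the germline median lay -0.45 from Ovary (1.46 against 1.91), which leaves dilution of the germ cell genes open because the gap is small. The testicular somatic list had its highest median in Testis, at percentile 100 there. This cannot exclude a library of another tissue under the Testis label, because lists reached or came near that percentile outside their named tissues. The sperm and spermatid list stood at 100 in Kidney, and ovarian somatic cells at 99.99 in Testis. A testis with few mature germ cells and a degraded sample also stay open and were not tested. No label gives season, maturity or RNA quality.

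The Skin library held muscle genes. Carry-over from the Muscle sample may explain them only if slow-type and fast-type genes lie below their Muscle level alike. Over 12 slow-type gene models the median log2 ratio of Skin to Muscle was 4.78, and over 18 fast-type models it was -4.56, which argues against carry-over for the slow-type genes. Of the slow-type models 50% were highest in Skin (6 of 12, with 4 in Heart, 1 in Gill and 1 in Muscle), and of the fast-type models 17 were highest in Muscle and 1 in Skin. A candidate explanation is slow-type muscle beneath the skin taken with the sample, a hypothesis found and tested on the same data.

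Pancreatic enzyme genes appeared in the Liver library at a small share of their Pancreas level. Over 17 exocrine genes the median share was 0.0438% in Liver against 0.000827% in Brain, the highest of the 8 other libraries of the same depth, a ratio of 52.9, which argues against reads misassigned alike between libraries. The shares in Liver lay between 0.0302% and 0.149%, with an interquartile range of 0.52 on the log2 scale; the test was first run on the 14 genes above an FPKM of 1000 in Pancreas (ratio 71.7, interquartile range 0.47) and then widened to those above 10. Liver genes appeared in turn in Pancreas and Testis. Hemopexin (C0J45_02696) stood at 65773 in Liver, 34.9 in Pancreas and 33.4 in Testis. Apolipoprotein A-I (C0J45_17850) stood at 37922, 17.4 and 33.2. A small amount of exocrine pancreas in the liver sample remains a hypothesis. Misassignment specific to these libraries was not tested, and it could also give like shares over the genes, so these values do not separate them. The leading Heart gene, the atrial myosin regulatory light chain (C0J45_15206, 17334 in Heart), was spread unevenly over libraries of that depth. It stood at 4.27 in Brain, 5.15 in Gill, 4.43 in Head_kidney, 4.17 in Kidney and 5.11 in Spleen. In Testis it stood at 2.02 and in Ovary at 0.232, and it was listed at 0 in Liver and Pancreas. Whether misassignment gave this spread was not tested.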
